A study of Mus musculus with 12 samples.

How the data were processed

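The series held 12 single-colour Agilent whole mouse genome arrays (design 014868) of mouse embryonic fibroblast RNA, 3 in each of 4 groups, with groups and replicate numbers taken from the sample labels. Per the labels' protocols, Atm-KO and Atm-WT cells were irradiated at 4.32 Gy and kept for 72 h, RNA was prepared with Trizol, and Cy3-labelled cRNA was hybridised. The dose rate is not given in the sources used here. Per the file headers, the deposited scanner files hold spot intensity extracted with Feature Extraction 10.7.1.1, with statistics of background subtraction and spatial detrending within each array, and the 75th percentiles below show that arrays were not brought to a common level. The submitters' processing notes name Agilent Feature Extraction 11.0 instead, and that difference was not resolved. Other deposited columns used were the median spot and local background intensity and the flags for spots well above background, saturated or outlying.

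The authors also deposited a matrix of log2 values, whose scale and centring were found from the values. Set against the scanner files over 41174 matched probes of its 41250, the columns followed log2 processed signal shifted by each array's 75th percentile and centred on each probe's median over the 12 arrays (largest absolute median 5e-04), with r of at least 0.99751 and slopes from 0.9986 to 1 after the same steps. It was used as an alternative.

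For the main values, control spots were left out, as were spots flagged as outliers unless all spots of the probe were, log2 processed signal was taken minus each array's 75th percentile, and spots of a probe were averaged. The files as read here carry accessions and no gene name column, so probes were named by matching the accession, without version, to a RefSeq gene table, a step chosen once the columns were known. Of 41174 probes, 25097 were named, giving 17305 genes, and unnamed accessions stayed as features of their own. A feature with several probes was represented by the probe with the highest mean log2 value over the 12 arrays. A feature was tested when it was well above background on all 3 arrays of at least 1 group, which left 18430. For 14 pairs of named gene and comparison with several tested probes, 0 had probes of opposite sign. No coordinates are given, since the builds of the files (mm9) and of the gene table differ. The 75th percentile of signal, 379 to 757 per array, is the nearest measure of depth, and the number of arrays limits the precision.

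A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with eBayes and Benjamini-Hochberg adjustment at 0.05. All groups share 1 estimate of the spread per gene, with 8 residual and 4.13 prior degrees of freedom. Comparisons were irradiated minus nonirradiated cells within each genotype, the difference of these effects (Atm-KO minus Atm-WT), and Atm-KO minus Atm-WT cells within each treatment. Where no probe of a gene was well above background on any array of 1 group, a fold is given as at least the bright group's mean over the dim group's mean, with each dim array's value set to the higher of its own signal and the lowest signal well above background on that array. A list's median was also computed with such genes at their bounds.

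Gene lists were tested with camera in limma, at a preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over lists within a comparison. The 22 lists were p53 target genes, DNA replication genes, mitosis genes, homologous recombination and Fanconi genes, end joining and damage signalling genes, interferon response genes, secreted inflammatory and senescence-associated genes, cell cycle inhibitor and senescence marker genes, extracellular matrix genes, smooth muscle and myofibroblast genes, skeletal muscle genes, epithelial genes, endothelial genes, macrophage and blood cell genes, adipocyte genes, neural and glial genes, oxidative stress genes, cholesterol synthesis genes, Hox genes, imprinted genes, sex-linked genes, and genes beside Atm on chromosome 9. Cdkn1a, Cdkn1c and Ncam1 each stand in 2 lists. The groups, the model, the lists, the alternatives other than those said to be chosen after seeing the data, and the rule for named genes were fixed before the data were examined. That rule names Atm and 10 fixed genes in each comparison, then, among genes called whose groups do not overlap and whose symbol is a gene name, the 8 highest and 8 lowest, and up to 3 called members per list with the smallest adjusted p. Some were left out of the text for length, and some genes are not reported here. For the fit with pairs, the same rule was applied after the data were seen.

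Whether replicate numbers pair the samples was checked from the correlation of same-numbered samples' deviations from their group means. It was 0.481 to 0.852 for irradiation in Atm-WT cells, 0.269 to 0.510 for irradiation in Atm-KO cells and 0.218 to 0.629 between genotypes in irradiated cells, all over 0.1, so numbers were taken to pair samples there. The own number gave the highest correlation for 3, 2 and 2 of the 3 numbers, in that order. Between genotypes in nonirradiated cells the correlation was -0.217 to 0.179, and numbers were not taken to pair samples. The pairing comes from the data, since the labels give the same numbers but no shared culture or day. Slide and scan batch were the same 3 groups of 4 arrays.

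The models were tested on simulated data, with 100 of 18430 genes changed per size. The fit without a block recovered 6% of genes changed by 1 log2 unit and 63% of those changed by 2 in the comparison of irradiation in Atm-WT cells, 9% and 67% in Atm-KO cells, 0% and 28% for the difference between genotypes, 5% and 58% between genotypes in nonirradiated cells and 7% and 64% in irradiated cells. For the fit with pairs as a block, other arrays were simulated, with the fitted pair differences added and the paired fit's spread. The shares were then 29% and 84%, 32% and 86%, and 2% and 48% for the first 3. These shares take the pairing as true, so they do not compare both fits on the same data. False calls numbered 2 to 5. A simulated shift of -0.5 in the mitosis list gave camera's adjusted p = 5.68e-09, and 0 other lists were called. Noise was drawn independently for each gene there, so this does not test list calls where genes of a list vary together.

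Alternatives tried were quantile normalization, scaling to the array median, normexp background correction (offset 50, on the median spot and background intensity, since the planned mean is not among the columns), the authors' log2 table, no filter on dim probes, a filter over all 12 arrays, the mean over a gene's probes, each probe on its own, slide as a random block or a fixed term, the replicate number and the pair as blocks, trend and robust variance, array weights, only the compared groups, stricter thresholds, and leaving out each array in turn. Added after seeing the data were leaving out all replicate 1 samples, with and without pairs, leaving out the 3 brightest arrays, list tests with pairs, and array weights estimated gene by gene, as was the division of the nonirradiated Atm-WT arrays between comparisons.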

Results

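Expression was measured in mouse embryonic fibroblasts with an intact Atm gene (Atm-WT) or without it (Atm-KO). Atm encodes the kinase that signals DNA double-strand breaks. Cells of both genotypes were either irradiated with 4.32 Gy or left nonirradiated, and RNA was taken after 72 h. Each of the 4 groups held 3 samples, and each sample was hybridised to 1 single-colour array, so 12 arrays were compared. The labels do not say that the replicates came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be partly technical. The 75th percentile of the processed signal ran from 379 to 757 between arrays, and 55.3% to 64.5% of probes were well above background. No spot was saturated. The number of arrays limits the precision of every value. Unless said otherwise, differences are log2 values with their limma standard errors, n = 3 arrays per group, and p-values are limma's after Benjamini-Hochberg adjustment over 18430 features, of which 12805 carried a gene name. In the 4 comparisons between groups, every gene called lay higher on all arrays of 1 group than on all arrays of the other. Chance alone gives this for 10% of unselected genes, but the calls select for it, so it adds no separate support.

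Atm transcript itself lay below the array's 75th percentile on every array. On the brighter of its probes, log2 signal relative to the array's 75th percentile was -3.55, -5.65 and -4.25 in nonirradiated Atm-WT samples 1 to 3, and -2.87, -4.60 and -4.60 in irradiated Atm-WT samples. In Atm-KO samples it was -5.43, -7.01 and -6.20 without irradiation and -5.67, -7.50 and -6.48 after it. The probe was well above background on 2 and 3 of the 3 Atm-WT arrays, nonirradiated and irradiated, and on 0 and 1 of the 3 Atm-KO arrays. The difference between genotypes was -1.73 ± 0.658 in nonirradiated cells, a fold of at least 1.96 with limma's adjusted p = 0.476, and -2.52 ± 0.658 in irradiated cells, with adjusted p = 0.225. On the other probe it was -1.11 ± 0.601 and -1.82 ± 0.601. Both probes lay lower in Atm-KO groups, but neither difference passed the test, and nonirradiated Atm-WT sample 2 was as dim as the number 1 samples of Atm-KO cells. Where these probes lie relative to the disrupted part of the gene is not known here, so they are a weak check of the labels. Of the 22 fixed lists, the genes beside Atm on chromosome 9 had a median genotype difference of -0.16 in nonirradiated cells, with camera's adjusted p = 0.217.

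**Figure D1:**
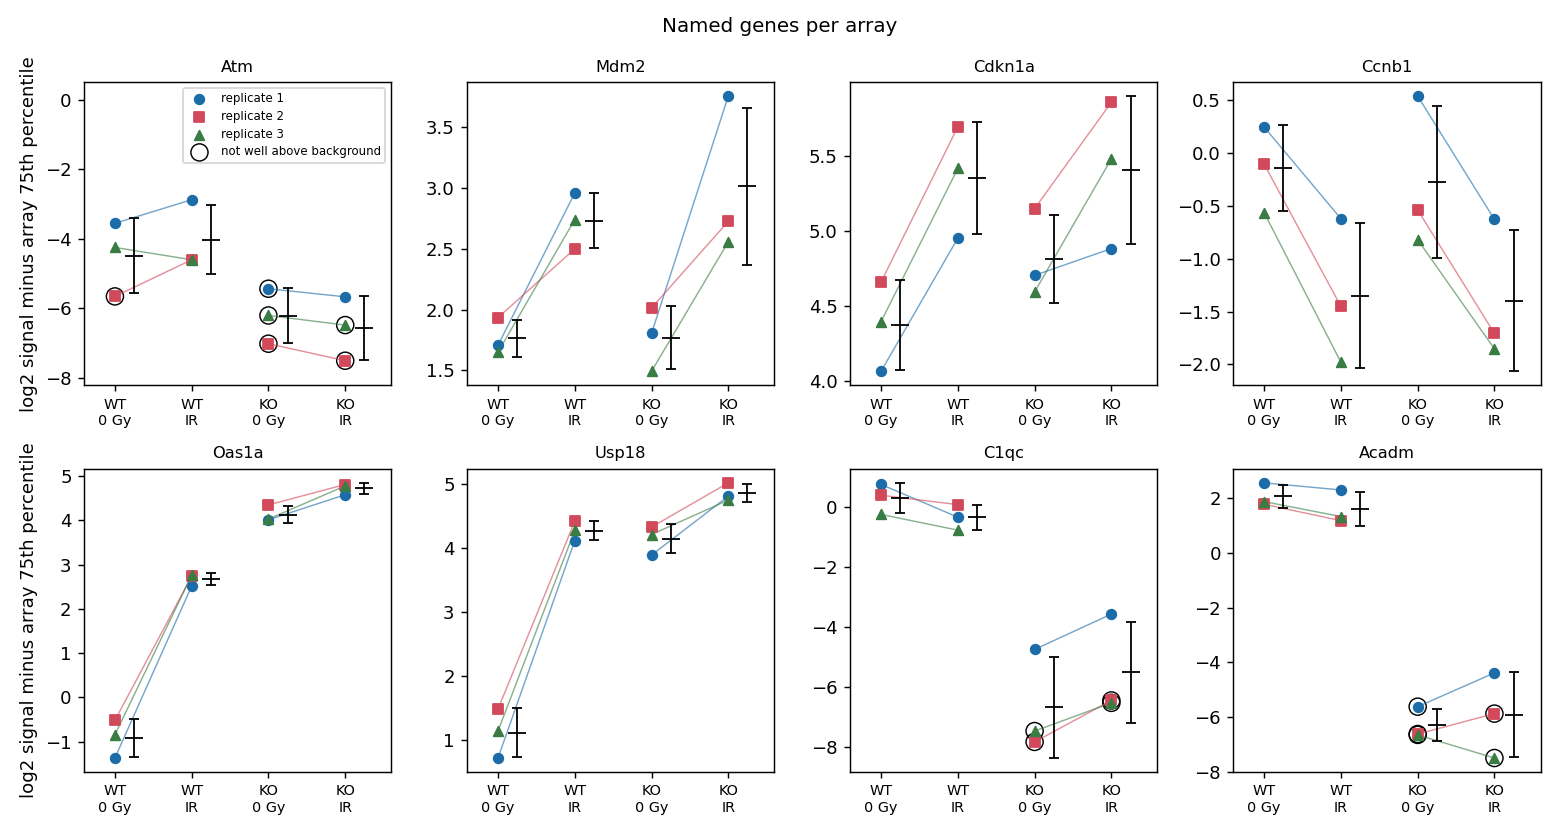
Log2 signal minus the array's 75th percentile for 8 genes in the 4 groups (WT and KO, nonirradiated marked 0 Gy and irradiated marked IR), where points are arrays, lines join same-numbered samples, bars are the mean and SD of 3 arrays, and circles mark spots not well above background. Oas1a was lowest in nonirradiated Atm-WT cells, at a mean of -0.91, and Acadm was at 2.07 there against -5.92 in irradiated Atm-KO cells.

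The first comparison asked how Atm-WT fibroblasts differed 72 h after irradiation from nonirradiated ones. Genes of the interferon response rose together. Of the 35 interferon response genes tested, which are the antiviral genes induced by type I interferon, 27 rose over all genes tested and 33 when adjusted over the list alone, and none fell. Their median was 2.44, a 5.42-fold rise. Irf7, a transcription factor that drives interferon genes, rose by 3.77 ± 0.354. Oas2 and Oas1a, sensors of double-stranded RNA, rose by 4.09 ± 0.474 and 3.58 ± 0.253, with 2.36 on the dimmer probe of Oas2. Zbp1, a sensor of unusual nucleic acid structures, rose by 3.85 ± 0.430. The antiviral enzyme Rsad2 rose by 4.02 ± 0.479, Trim30a by 4.01 ± 0.560 and Ifi44 by 3.76 ± 0.516. Tgtp1, an interferon-induced GTPase outside the list, rose by 3.65 ± 0.441, with 1.86 on its dimmer probe. Trim30d was not well above background in nonirradiated cells and rose at least 6.26-fold. Usp18, which restrains interferon signalling, rose by 3.15 ± 0.25, and Oasl2 by 2.95 ± 0.270. Probes of close relatives (Oas1a, Oas1d and Oas1f, or Trim30a and Trim30d) may share signal, which the arrays do not resolve. The list's shift passed camera, limma's test of a list against other genes, with adjusted p = 8.85e-104 at the preset correlation and adjusted p = 0.000136 with an estimated correlation. The rise was measured on both slides that held Atm-WT arrays, with medians of 2.51 and 2.31.

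In all, 82 genes changed in irradiated Atm-WT cells, 78 higher and 4 lower, and 59 of them carried a name. The adjusted p-values of the genes above ran from 9.33e-05 for Oas1a to 0.00852 for Trim30d. The 3 named genes that fell were Calca, the calcitonin gene, by 1.81 ± 0.327 (-1.16 on its dimmer probe), Mia, a secreted cartilage protein, by 1.80 ± 0.341, and Rpa1, the large subunit of the single-stranded DNA binding protein RPA, by 1.23 ± 0.238. Calca, Mia and Rpa1 lost their calls when 8, 10 and 10 of the 12 arrays were left out singly, with adjusted p up to 0.136, 0.166 and 0.225, and kept their direction but not their calls under normexp background correction. So did Trim30d, Rsad2, Trim30a and Ifi44, at 0.51, 2.31, 1.71 and 2.02. For irradiation in Atm-WT cells the count fell to 49 without sample 3 of the irradiated group, and was 139 with slide as a fixed term.

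Genes of proliferation lay lower in irradiated Atm-WT cells, but no single member was called over all genes tested. All 39 DNA replication genes tested had a negative difference, with a median of -0.61 and camera's adjusted p = 1e-21, but adjusted p = 0.071 with an estimated correlation. Of 38 mitosis genes, 37 had a negative difference, 11 fell when adjusted over the list alone, and the median was -0.84 (camera adjusted p = 2.66e-19, but adjusted p = 0.154 with an estimated correlation). Ccnb1, the cyclin of mitotic entry, was at -1.21 ± 0.460, Mki67, a marker of cycling cells, at -0.90 ± 0.660, and Mcm2, a subunit of the replicative helicase, at -0.69 ± 0.229. The 22 homologous recombination and Fanconi genes had a median of -0.48 (camera adjusted p = 8.37e-06, but adjusted p = 0.154 with an estimated correlation). Targets of p53, the damage-activated transcription factor, lay higher, with a median of 0.56 over 34 genes (camera adjusted p = 4.32e-10, but adjusted p = 0.110 with an estimated correlation), and 1 rose when adjusted over the list alone. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was at 0.98 ± 0.313, Mdm2, the ubiquitin ligase of p53, at 0.97 ± 0.313 and Ccng1 at 0.64 ± 0.306. Of 26 secreted inflammatory and senescence-associated genes, none was called, 0 when adjusted over the list alone, and the median was 0.63 (camera adjusted p = 5.17e-05, but adjusted p = 0.209 with an estimated correlation). Replicate 1 samples of all 4 groups stood apart in these groups: mitosis genes lay 0.66 higher and p53 targets -0.41 relative to replicates 2 and 3 (medians).

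Same-numbered samples varied together, so the same values were also fitted with the pair of same-numbered samples as a block. Then 417 genes changed in Atm-WT cells, 302 higher and 115 lower. Single members of the proliferation and p53 lists passed this test over all genes tested. Ccnb1 fell by 1.21 ± 0.184 (adjusted p = 0.012), as did Ccna2, its S-phase relative, by 1.1 ± 0.194 and the mitotic kinase Melk by 1.13 ± 0.198, and 9 mitosis genes fell in all (30 when adjusted over the list alone). Prim1, a primase subunit, and Rfc4, a clamp loader subunit, were among 4 DNA replication genes that fell (25 when adjusted over the list alone), by 0.97 ± 0.176 and 0.89 ± 0.169. Cdkn1a rose by 0.98 ± 0.193 (adjusted p = 0.0353), and Gdf15, Cd80 and Zfp365 were the other 3 p53 targets of the 4 that rose. Adjusted over the list alone, 19 p53 targets rose and 1 fell. The mitosis, p53 and homologous recombination lists then passed at adjusted p = 0.0377 with an estimated correlation, and DNA replication did not, at adjusted p = 0.058 with an estimated correlation. Of the secreted genes, 5 rose and 1 fell (13 and 1 when adjusted over the list alone), among them the chemokine Ccl8 by 1.57 ± 0.231 and the protease Mmp10 by 1.21 ± 0.226. Without replicate 1, that fit called 109 genes.

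**Figure D2:**
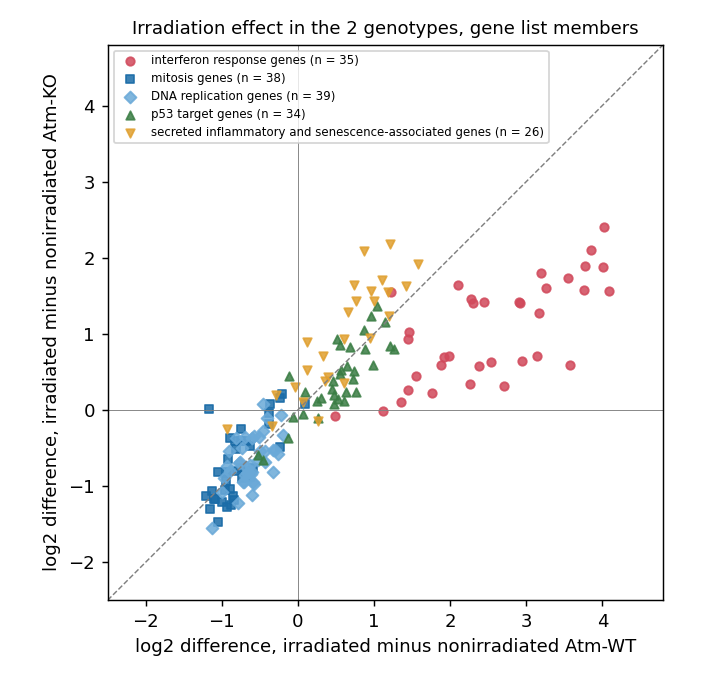
Log2 difference after irradiation in Atm-WT cells (x axis) against Atm-KO cells (y axis) for the tested members of 5 gene lists, each point a gene and the dashed line marking equal differences. Of the interferon response genes, 34 of 35 lay below the line, with medians of 2.44 and 1.02, while mitosis genes lay near it, with medians of -0.84 and -0.80.

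The second comparison asked the same of Atm-KO fibroblasts. Interferon response genes lay higher after irradiation here too, with a median of 1.02 over 35 genes, and 20 rose when adjusted over the list alone, though none over all genes tested. Mitosis genes, DNA replication genes and homologous recombination and Fanconi genes lay lower, with medians of -0.80, -0.69 and -0.47. Secreted inflammatory genes lay higher, with a median of 0.94, and p53 targets had a median of 0.39. Limma called 1 gene over all genes tested, while 1463 had an unadjusted p under 0.05: Lhx5, a LIM homeobox gene not well above background in nonirradiated cells, rose at least 4.07-fold (adjusted p = 0.0194), but stood at 0.75 without a call under normexp background correction. The interferon list's shift passed camera with adjusted p = 6.14e-27, and adjusted p = 0.0167 with an estimated correlation, and its medians were 1.5 and 0.83 on the slides that held Atm-KO arrays. Of the other lists named, camera's adjusted p was 3.88e-13 for mitosis (14 lower when adjusted over the list alone), 5.87e-19 for DNA replication (16), 0.000998 for homologous recombination (4), 8.01e-12 for secreted genes (6 higher) and 6.92e-07 for p53 targets (0). Each lost the call with an estimated correlation: adjusted p = 0.276, 0.0679, 0.276, 0.0679 and 0.205, in the same order. Cholesterol synthesis genes had a median of -0.34 (camera adjusted p = 0.0191, but adjusted p = 0.865 with an estimated correlation), and the call was lost without nonirradiated sample 1, irradiated sample 2 or irradiated sample 3 of Atm-KO (adjusted p = 0.549, 0.158 and 0.316). Lhx5 lost its call without 7 of the 12 arrays left out singly, all 6 Atm-KO arrays and nonirradiated Atm-WT sample 2, and 2 genes were called without irradiated Atm-WT sample 1 or 2.

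With the pair of same-numbered samples as a block, 377 genes changed in Atm-KO cells, 218 higher and 159 lower. The pairing is less certain here, since Atm-KO sample 2 correlated less with its own number than with another (0.269 against 0.335). Replicate 1 samples standing apart could also give such correlations, so these calls depend on a pairing that is not shown. Ccnb1 fell by 1.12 ± 0.184 (adjusted p = 0.0234), Birc5, an inhibitor of apoptosis that acts in mitosis, by 1.47 ± 0.234, and Bub1b, a spindle checkpoint kinase, by 1.27 ± 0.177, among 11 mitosis genes (23 when adjusted over the list alone). The helicase subunit Mcm5 fell by 1.22 ± 0.220, and Tyms and Tk1, enzymes of thymidylate supply, by 0.94 ± 0.171 and 1.55 ± 0.291, among 5 DNA replication genes (27 when adjusted over the list alone). Of p53 targets, Mdm2 rose by 1.24 ± 0.257 (adjusted p = 0.0489), Pmaip1, which promotes apoptosis, by 1.36 ± 0.271 and Gdf15 by 0.81 ± 0.168. Adjusted over the list alone, 14 p53 targets were higher and 2 lower. Of the interferon list, 9 rose (28 when adjusted over the list alone), among them Zbp1 by 2.10 ± 0.213 and the chemokine Cxcl10 by 1.80 ± 0.182. Of the secreted genes, 9 rose (16 when adjusted over the list alone), among them Ccl8 by 1.91 ± 0.231, and Mmp10 and Areg, a growth factor of the EGF family, by 2.18 ± 0.226 and 1.44 ± 0.192, each measured on 2 of 3 nonirradiated arrays. Lmnb1, a nuclear lamina protein whose loss marks senescent cells, fell by 1.35 ± 0.182, and by 0.95 ± 0.182 in Atm-WT cells. Cd53 and C1qc of the macrophage and blood cell list rose by 1.63 ± 0.243 and 1.17 ± 0.206. Both were well above background on 1 of 3 nonirradiated Atm-KO arrays, and on 2 and 1 of 3 irradiated ones, so their rises are measured largely against background. That list's shift passed camera in this fit (adjusted p = 0.0379, but adjusted p = 0.585 with an estimated correlation). In this fit no list named here passed with an estimated correlation, with adjusted p = 0.0854 for mitosis, DNA replication, homologous recombination, p53 targets and secreted genes and 0.117 for interferon genes. Without replicate 1, the paired fit called 0 genes in Atm-KO cells, where Ccnb1 and Mdm2 stood at -1.10 and 0.89.

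The responses of both genotypes ran in the same direction. All 82 genes called in Atm-WT cells had the same sign in Atm-KO cells, with medians of 2.55 and 1.27. Across genes, which are not independent replicates, the irradiation effects correlated with Pearson's r = 0.653 and Spearman's rho = 0.636. In the paired fit, 112 genes rose in both genotypes and 66 fell in both, where independent lists would share 3.57 and 0.992, and 0 moved in opposite directions, where 2.61 and 1.36 were expected. On every slide, nonirradiated samples lay at positions 1 and 3 and irradiated samples at positions 2 and 4, so position and irradiation cannot be told apart.

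The third comparison asked whether the response to irradiation differed between genotypes. Interferon response genes rose less in Atm-KO than in Atm-WT cells. The difference had a median of -1.51, and 1 member, Oas1a, was called over all genes tested at -2.99 ± 0.357 (adjusted p = 0.0412), while 26 members were lower when adjusted over the list alone. Oas1a rose by 3.58 in Atm-WT cells and was 0.59 higher in irradiated than in nonirradiated Atm-KO cells. With each gene centred on its mean over 12 arrays, the median of the members was -1.94 ± 0.208 (SD, n = 3) in nonirradiated Atm-WT cells, 0.56 ± 0.0459 in irradiated Atm-WT cells, 0.13 ± 0.171 in nonirradiated Atm-KO cells and 1.18 ± 0.304 in irradiated Atm-KO cells. Camera's adjusted p was 8.29e-84, and adjusted p = 0.000305 with an estimated correlation. Other lists that passed camera were macrophage and blood cell genes, with a median difference of 0.87 (adjusted p = 6.44e-09, but adjusted p = 0.235 with an estimated correlation), and secreted inflammatory genes, at 0.38 (adjusted p = 3.04e-05, but adjusted p = 0.399 with an estimated correlation). Of the 12 macrophage genes, 6 were not well above background on all Atm-KO arrays, and the other 6 had a median difference of 0.47. For p53 targets, DNA replication and mitosis genes the median differences were -0.12, -0.09 and 0.01, and the test did not call them. Limma called 1 gene in all, and 166 had an unadjusted p under 0.05. With the pair as a block, 4 genes were called, all lower: Oas1a, its relative Oas1f at -2.81 ± 0.260, Usp18 at -2.43 ± 0.258 and Isg15, the ubiquitin-like product of the interferon response, at -2.40 ± 0.257. That fit gave the interferon list adjusted p = 0.130 with an estimated correlation, and called neural and glial genes, at a median of 0.34 (adjusted p = 0.00683, but adjusted p = 0.189 with an estimated correlation). Under normexp background correction Oas1a stood at -2.60 without a call, and it also lost its call when any array other than nonirradiated Atm-WT sample 2 was left out, with adjusted p from 0.0724 to 0.258.

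**Figure D3:**
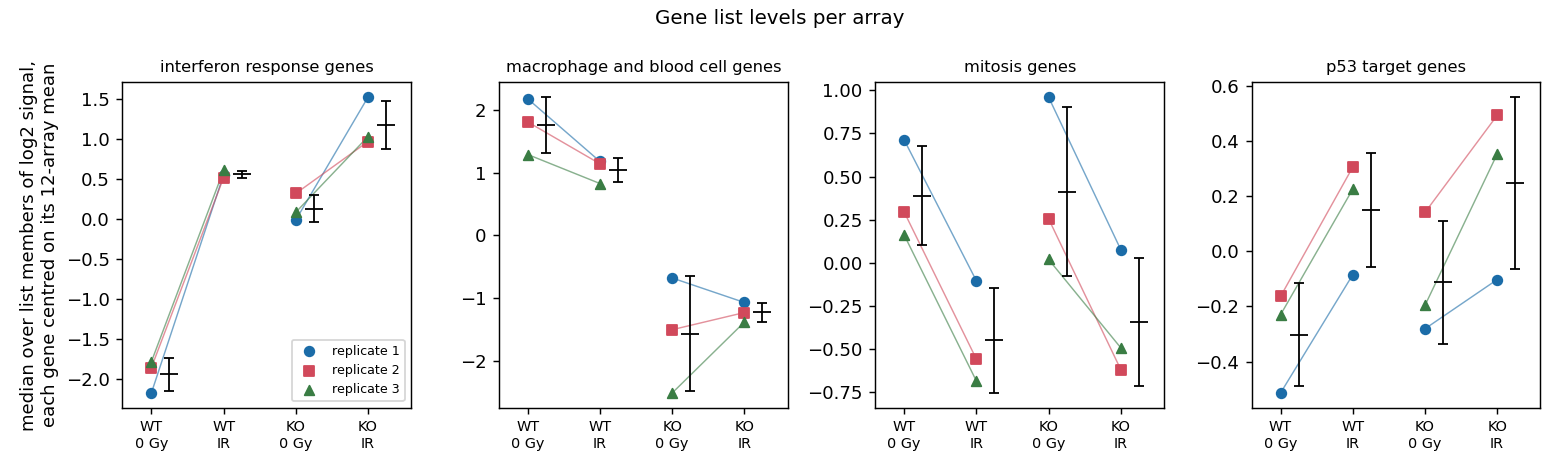
Median log2 signal over the members of 4 gene lists per array, each gene centred on its mean over 12 arrays, in the 4 groups, where points are arrays, lines join same-numbered samples, and bars are the mean and SD of 3 arrays. Interferon response genes stood at -1.94 in nonirradiated Atm-WT cells and 0.13 in nonirradiated Atm-KO cells, and macrophage and blood cell genes at 1.76 and -1.56.

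The fourth comparison asked how Atm-KO fibroblasts differed from Atm-WT fibroblasts without irradiation. Interferon response genes were higher in Atm-KO cells: of 35 tested, 24 were called and 31 when adjusted over the list alone, with a median of 2.16. Oas1a was higher by 5.04 ± 0.253 (adjusted p = 2.27e-06), which is 32.8-fold, Oas1f by 4.70 ± 0.378, Irf7 by 3.08 ± 0.354, Usp18 by 3.02 ± 0.25 and Oasl2 by 2.70 ± 0.270. Macrophage and blood cell genes were lower: of 12 tested, 11 were called and 12 when adjusted over the list alone, with a median of -2.89, or -2.52 with members not well above background at their bounds. C1qc and C1qa, complement subunits made by macrophages, were at -6.97 ± 0.840 and -6.17 ± 0.846, with 1 of 3 nonirradiated Atm-KO arrays well above background for each. The macrophage surface receptor Adgre1 was at least 13.9-fold lower, the myeloid inhibitory receptor Pirb, outside the list, at least 12.3-fold lower, and the lysozyme gene Lyz2 was at -2.59 ± 0.273. Normexp background correction, whose offset of 50 pulls dim values together, gave smaller differences, with C1qc, C1qa, Adgre1, Pirb and Lyz2 still called at -3.25, -2.67, -2.29, -1.82 and -1.74.

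In all, 158 genes differed between the genotypes without irradiation, 72 higher and 86 lower in Atm-KO cells, and 136 carried a name. Acadm, the medium-chain fatty acid dehydrogenase of mitochondria, was at least 185-fold lower (adjusted p = 8.92e-05), or called at -4.65 under normexp, and Gpd1, the cytosolic glycerol phosphate dehydrogenase, was 3.22 ± 0.379 higher, with 2 of 3 nonirradiated Atm-WT arrays well above background, but 0.83 without a call under normexp background correction. Oas1d, Trim30d and the plakophilin gene Pkp1 were not well above background in nonirradiated Atm-WT cells and lay at least 2.25, 3.00 and 2.14-fold higher, but at -0.21, -0.10 and -0.30 under that correction, and 2 of 3 nonirradiated Atm-KO arrays measured Pkp1. Of 14 imprinted genes, which are expressed from 1 parental copy, Dlk1, an inhibitor of adipocyte formation, was at -2.17 ± 0.247 and Cdkn1c, an inhibitor of cyclin-dependent kinases, at -1.71 ± 0.337, and 2 were lower and 1 higher when adjusted over the list alone. Their median of -0.38 passed camera (adjusted p = 0.00327, and adjusted p = 0.0413 with an estimated correlation). Of 7 adipocyte genes, Lpl, the lipoprotein lipase, was called at -2.54 ± 0.491 (2 lower when adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.000422, and adjusted p = 0.0275 with an estimated correlation). Hox genes had a median of -0.61 (adjusted p = 1.2e-05, but adjusted p = 0.446 with an estimated correlation), with Hoxd3 called at -1.64 ± 0.335, measured on 2 of 3 nonirradiated Atm-KO arrays (3 lower and 1 higher when adjusted over the list alone). Cholesterol synthesis genes had a median of -0.43 (adjusted p = 3.57e-06, but adjusted p = 0.388 with an estimated correlation), with 1 lower when adjusted over the list alone. The endothelial cadherin Cdh5 was at -3.10 ± 0.614, measured on 1 of 3 nonirradiated Atm-KO arrays. Under normexp Cdkn1c, Hoxd3 and Cdh5 stood at -1.44, -0.84 and -1.25 without a call. The interferon and macrophage lists passed camera with adjusted p = 1.7e-65 and 1.56e-36, and with adjusted p = 0.000763 and 0.00399 with an estimated correlation.

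Slide was mostly aligned with genotype, and a single slide held all 4 groups, with 1 array each. Its Atm-WT arrays were sample 3 and its Atm-KO arrays sample 1, and replicate 1 samples stood apart in 8274 genes. Genotype values on that slide, or with slide as a term, thus mix genotype with replicate 1. On that slide, the nonirradiated genotype medians were 1.78 for interferon genes, -2.04 for macrophage genes, -0.26 for imprinted genes, -0.43 for adipocyte genes, -0.25 for Hox genes and 0.06 for cholesterol synthesis genes, so the last did not hold there. With slide as a fixed term, 34 genes remained called, 33 of them among the 158. Oas1a (4.83), Oas1f, Oas1d, Gpd1, Usp18, Oasl2, Acadm, C1qc (-4.55), C1qa, Adgre1, Pirb, Lyz2 and Dlk1 (-2.34) kept their calls. Irf7 (2.43), Cdkn1c (-1.66), Cdh5 (-1.66), Lpl (-1.71), Hoxd3 (-1.38), and Pkp1 and Trim30d, both near background in Atm-WT cells, kept their direction but not their calls. So did Oas2 (2.61), Trim30a (4.06), Tyrobp (-3.44) of the macrophage list, and Ctss (-3.05) and Ms4a7 (-2.81), macrophage genes outside it. Left out singly, nonirradiated Atm-WT samples 2 and 3 moved the count to 88 and 103, and nonirradiated Atm-KO samples 2 and 3 to 57 and 74. Of the 25 named genes called, 17 kept their calls whichever array was left out, and Trim30d, Pkp1, Lpl, Cdh5, Cdkn1c and Hoxd3 were among the 8 that did not (adjusted p up to 0.254, for Hoxd3). Without all replicate 1 samples, the count for genotype in nonirradiated cells was 1580, with 156 of the 158 among them, and the imprinted list lost its call. The samples left share no slide between genotypes, and only those of Atm-KO cells expressed Xist. Genotype, slide and sex therefore cannot be told apart in that count. Of the genes higher in Atm-KO cells, 51 also rose with irradiation in Atm-WT cells, where independent lists would share 0.305. Both comparisons use the same 3 nonirradiated Atm-WT arrays. Their effects correlated across genes at r = 0.342, with a covariance of 0.0868. Simulated unchanged groups compared against a shared simulated control group gave means of 0.471 and 0.104, a covariance difference of -0.0174. The 3 nonirradiated Atm-WT arrays were also divided, 1 for one comparison and 2 for the other, in 6 ways. A lone array is assumed there to vary like the other groups. Then r ran from -0.111 to 0.0954, while the interferon list's medians stayed at 2.28 to 2.68 for irradiation and 1.93 to 2.27 for genotype. Shared calls do not settle the question there, since fewer genes are called with the arrays divided. In 100 simulations without any effect, 0 genes were higher in both, which does not cover genes with an effect. Part of the overlap of 51 may come from the shared arrays, but these values do not show how much.

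The fifth comparison set irradiated Atm-KO against irradiated Atm-WT cells. Macrophage and blood cell genes were again lower in Atm-KO cells, with a median of -2.20 over 12 genes, 5 called and 11 lower when adjusted over the list alone. C1qc was at -5.16 ± 0.840, with 1 of 3 irradiated Atm-KO arrays well above background, Lyz2 at -2.14 ± 0.273, and Laptm5, a lysosomal protein of blood cells, at least 4.88-fold lower. Interferon genes were 0.44 higher in the median, with 2 called, Oas1a at 2.05 ± 0.253 and the chemokine Ccl5 at 2.20 ± 0.303, and 4 when adjusted over the list alone. Acadm was at -7.53 ± 0.634 (adjusted p = 0.000895), with 1 of 3 irradiated Atm-KO arrays well above background. Tslp, a cytokine of barrier tissues, was higher by 2.84 ± 0.302 (adjusted p = 0.00385), Gpd1 by 2.83 ± 0.379, and Ptgds, a prostaglandin synthase, lower at -5.37 ± 0.827. Dlk1 and Cdkn1c were at -2.14 ± 0.247 and -2.10 ± 0.337. In all, 38 genes differed, 11 higher and 27 lower in Atm-KO cells.

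The list shifts passed camera in irradiated cells with adjusted p = 2.01e-34 for macrophage genes (adjusted p = 0.00948 with an estimated correlation), 5.19e-14 for interferon genes (adjusted p = 0.0418 with an estimated correlation) and 0.00163 for imprinted genes, with a median of -0.29 (adjusted p = 0.0418 with an estimated correlation). Cholesterol synthesis genes had a median of -0.68 (adjusted p = 1.36e-13, but adjusted p = 0.0817 with an estimated correlation), Hox genes -0.48 (adjusted p = 8.13e-05, but adjusted p = 0.476 with an estimated correlation) and adipocyte genes -0.37 (adjusted p = 0.00749, but adjusted p = 0.0754 with an estimated correlation). Secreted inflammatory genes had a median of 0.23 (adjusted p = 0.00163, but adjusted p = 0.452 with an estimated correlation), with the chemokine Ccl20 called and 2 when adjusted over the list alone. Without irradiated Atm-WT sample 1 the secreted list stood at -0.0636, and the adipocyte and imprinted lists lost their calls (adjusted p = 0.277 and 0.0549). Without irradiated Atm-KO sample 1, the secreted and adipocyte lists lost theirs (adjusted p = 0.416 and 0.0611). On the slide with all 4 groups, again with Atm-KO sample 1 against Atm-WT sample 3, the medians were 0.72 for interferon genes, -1.89 for macrophage genes, -0.85 for cholesterol synthesis genes and -0.03 for imprinted genes.

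For genotype in irradiated cells, 3 genes were called with slide as a fixed term, among them Acadm (-6.19) and C1qc (-2.74), and 140 with the replicate number as a block. The numbers were taken to pair samples here, but sample 3 correlated less with its own number than with another (0.218 against 0.341). Same-numbered samples also differed between genotypes in Xist and Y-linked genes. Replicate 1 samples standing apart in all groups could give such a correlation, so pairing is not shown. Left out singly, irradiated Atm-WT samples 2 and 3 moved the count to 3 and 23, irradiated Atm-KO samples 1, 2 and 3 to 104, 6 and 5, and nonirradiated Atm-KO sample 1 to 58. Of the 20 named genes called, Acadm and Tslp kept their calls whichever array was left out, and 18 lost them for at least 1 array. Under normexp background correction Tslp, Gpd1 and Ccl20 stood at 1.63, 1.42 and 1.07 and Lyz2 and Laptm5 at -1.09 and -0.42, all without a call. Without all replicate 1 samples, 1044 genes were called, all 38 among them, but slide and sex again followed genotype in the samples left.

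The remaining fixed lists showed no camera call in the 12-array fit. These were end joining and damage signalling genes, cell cycle inhibitor and senescence marker genes, extracellular matrix genes, smooth muscle and myofibroblast genes, skeletal muscle genes, epithelial genes, endothelial genes, neural and glial genes, oxidative stress genes and genes beside Atm on chromosome 9. Their medians lay between -0.35, for neural genes after irradiation of Atm-WT cells, and 0.38, for the endothelial genes' difference between the irradiation effects, and the smallest adjusted p was 0.132. In the fit without pairs, their only members called were Cdkn1c, Pkp1 and Cdh5, named above. Of the sex-linked genes, 5 were on the array and 0 were tested. Macrophage genes had a median of -0.59 after irradiation of Atm-WT cells (camera adjusted p = 0.00106, but adjusted p = 0.356 with an estimated correlation), a call lost without nonirradiated sample 1 or irradiated sample 3 of Atm-WT (adjusted p = 0.104 and 0.0556). Col1a1, the main collagen chain of fibroblasts, and Acta2, the smooth muscle actin, lay between -0.27 and -0.02 in every comparison, without a call. Trp53 and Cdkn2a, which encode p53 and its activator, were not called in any comparison either.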

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

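The tests of slide, scaling and cell content below were chosen only after the results were seen, while the regroupings of samples were planned before, except the count over all 32 that part every pair.

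Interferon response genes rose less with irradiation in Atm-KO than in Atm-WT cells, with Oas1a at -2.99 and the list median at -1.51, and they already stood higher in Atm-KO cells without irradiation. Loss of Atm may leave DNA damage that keeps interferon signalling on, so that irradiation adds less; that account fits the order of the 4 group levels, and neither damage nor interferon was measured here. Slide is an unlikely cause of the higher start, since with slide as a term the list mean differed by 2.10 ± 0.227, against 2.07 without, and scaling is unlikely too, since quantile normalization gave a list median of 2.06 against 2.16. The slide term rests on the 1 slide with both genotypes, where Atm-KO sample 1 meets Atm-WT sample 3. Interferon genes lay at -0.14 in replicate 1 samples relative to the other replicates (median). RNA of macrophages or other blood cells could carry interferon genes, but those genes were at -2.89 in nonirradiated Atm-KO cells, the opposite of what that would give. Of 100 splits of samples within genotypes, 13 gave the list a median as far from 0, up to 3.07 in size, and 9 gave as many calls, up to 8 against 1, but they carry the irradiation effect itself and so do not decide on chance: exchanging the irradiation labels throughout 1 genotype, among all 32 splits parting every same-numbered pair, gave 334 calls and a median of 3.72 in size, while camera gave adjusted p = 0.000305 with an estimated correlation, or 0.130 with pairs as a block.

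Macrophage and blood cell genes lay lower in Atm-KO cells in both treatments, and their difference between the irradiation effects, called by camera's test of that difference, was 0.87 (adjusted p = 0.235 with an estimated correlation, without a call), or 0.47 over the 6 of 12 members well above background on all Atm-KO arrays. Fewer macrophages in the Atm-KO cultures might explain this, and a second list of such genes, chosen for the purpose, had a median of -1.38 in nonirradiated cells. Of its 20 genes 10 were tested, 8 lay lower and 4 were called lower, while P2ry6 stood at 0.27. Since not all members fell together, fewer such cells and lower expression within cells cannot be separated here. Slide could account for part but not all, since with slide as a term the list mean was at -2.46 ± 0.25 against -3.64 without, and scaling did not account for it, with -2.82 under quantile normalization. The slide term rests on the 1 slide with both genotypes, where Atm-KO sample 1 meets Atm-WT sample 3. Macrophage genes lay 0.61 higher in replicate 1 samples (median), so the part credited to slide may come from replicate 1 instead.

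Secreted inflammatory and senescence-associated genes had a median difference of 0.38 between the irradiation effects, also called by that test, but without a call at adjusted p = 0.399 with an estimated correlation. The call was lost without all replicate 1 samples, and the cause was not tested.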

How the results depend on the processing

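The alternatives that leave out all replicate 1 samples, leave out the 3 brightest arrays, pair without replicate 1 or weight arrays gene by gene were chosen only after the results were seen. Without replicate 1, and in irradiated cells also without the 3 brightest arrays, slide and sex followed genotype. Genotype counts there do not separate genotype from slide or sex. Counts below are genes called, against 82 for irradiation in Atm-WT cells, 1 for irradiation in Atm-KO cells, 1 for the difference of the irradiation effect between genotypes, 158 for genotype in nonirradiated cells and 38 for genotype in irradiated cells, and settings not given for a comparison stayed within 1.5-fold. Irradiation in Atm-WT cells gave 46 with normexp, 139 with slide as a fixed term, 230 with the replicate number as a block, 417 with the pair of same-numbered samples as a block, 2817 with array weights, 44 in a fit of the compared groups alone, 49 at an adjusted p under 0.01, 49 without irradiated sample 3 and up to 101 (irradiated Atm-KO sample 1) when arrays were left out singly, 167 without replicate 1 and 256 with weights gene by gene. Irradiation in Atm-KO cells gave 0 with quantile normalization, array median scaling, normexp, no filter, the filter over 12 arrays, trend and robust variance, the compared groups alone, 0.01, without replicate 1, without the 3 brightest arrays and with pairs without replicate 1, 43 with the number block, 377 with the pair block, 4799 with array weights and 1064 with weights gene by gene, and 0 to 2 when arrays were left out singly. The difference of the irradiation effect gave 2 with quantile normalization and with trend and robust variance, 0 with array median scaling, normexp, no filter, each probe alone, slide as a fixed term, 0.01 and the 3 settings without replicate 1 or the brightest arrays, 5 with the number block, 4 with the pair block, 178 with array weights and 15 with weights gene by gene, and 0 to 1 when arrays were left out singly. Genotype in nonirradiated cells gave 70 with normexp, 103 with no filter, 87 with the filter over 12 arrays, 34 with slide as a fixed term, 315 with the number block, 2609 with array weights, 66 at 0.01, 1580 without replicate 1, 419 without the 3 brightest arrays, 1308 with weights gene by gene, and 57, 74, 88 and 103 when nonirradiated Atm-KO samples 2 and 3 and Atm-WT samples 2 and 3 were left out, and up to 225 without irradiated Atm-KO sample 1. Genotype in irradiated cells gave 63 with array median scaling, 14 with normexp, 20 with no filter, 15 with the filter over 12 arrays, 3 with slide as a fixed term, 140 with the number block, 11964 with array weights, 23 with the compared groups alone, 4 at 0.01, 1044 without replicate 1, 188 without the 3 brightest arrays, 1881 with weights gene by gene, and 3, 23, 58, 104, 6 and 5 when single arrays were left out, as given above. Of 105 list tests, 30 passed, against 47 with normexp, 10 with an estimated correlation, 17 with fry and 16 with fry and slide as a random block, and 30 to 45 when arrays were left out singly. The default array weights did not converge and gave 20.9 and 25.5 to irradiated sample 3 of either genotype, so those counts are not used. With pairs as a block, single proliferation, p53, secreted, macrophage, lamina and interferon genes gained calls, as did the neural list's difference between genotypes and, in Atm-KO cells, the macrophage list. With an estimated correlation the mitosis, p53 and homologous recombination lists gained a call in Atm-WT cells, and the interferon list lost its call in Atm-KO cells and for the difference between genotypes. Among other fixed lists, Cldn7 (epithelial), Mest (imprinted) and Exo1 (homologous recombination) gained calls as lower in both genotypes. In Atm-KO cells, Spp1 (extracellular matrix) and Hmga2 (senescence marker) gained calls as higher, and Cdkn1c as lower. The block changed no other call stated. Over all genes, array median scaling moved the median difference to -0.128 and -0.109 for irradiation in Atm-WT and Atm-KO cells, and normexp to -0.137 for irradiation in Atm-WT cells, 0.138 for the difference between genotypes and -0.108 for genotype in nonirradiated cells. Oas1d, Trim30d and Pkp1 reversed under normexp for genotype in nonirradiated cells, at -0.21, -0.10 and -0.30. A list reversed, secreted inflammatory and senescence-associated genes: genotype in irradiated cells moved it by 0.23, against -0.0636 without irradiated Atm-WT sample 1, 0.45 without irradiated Atm-KO sample 3, and -0.0507 both without replicate 1 and without the 3 brightest arrays. With arrays left out singly, named genes kept their side of the threshold in 1203 results and lost a call in 189, and lists kept theirs in 1187, gained a call in 63 and lost it in 9. The irradiation effects correlated at 0.793 over called genes. For results that did not hold, the cause was not tested. Signal near background limits what dim genes show, Atm among them. Every alternative fixed beforehand was run, except that normexp used median in place of mean spot intensity.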

Other observations

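All tests in this part were chosen only after the results were seen, except the regroupings of samples other than the count over all 32 that part every pair.

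Xist and Y-linked genes, which were not part of the tested comparisons, differed between sample numbers. The number 1 pair of Atm-WT cells and the number 2 and 3 pairs of Atm-KO cells expressed Xist, at -1.49 and -0.61 in the former, while the other samples did not. Same-numbered irradiated and nonirradiated samples were alike in these genes. Sex by these genes therefore differed between the genotypes' samples as well as within them.

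The regroupings gave these counts. For each comparison of 3 against 3 arrays, 1 of 10 splits, the real one, gave as many calls as the real split. The real splits gave 82, 1, 158 and 38 calls for irradiation in Atm-WT cells, irradiation in Atm-KO cells, and genotype in nonirradiated and irradiated cells, and the highest other splits gave 7, 0, 0 and 0. So few splits cannot give a share under 0.05. Where 7 genes were called, number 1 samples of both treatments lay on the same side, and the splits that part all 3 pairs, 4 with the real one, gave 0 calls otherwise. The correlation of both irradiation effects over genes, 0.653, was reached by 1 of 100 splits, the real one, and the highest other was 0.612. Of all 32 splits that parted every pair of same-numbered samples, 1, the real one, reached it, and the highest other was 0.502. Exchanging the irradiation labels throughout 1 genotype gave -0.653, the same size with the opposite sign. The shares of 1 in 100 and 1 in 32 lay under 0.05, and 1 in 32 is the smallest that the splits parting every pair can give. But these splits carry the irradiation effect itself. They do not show the spread without an effect, and so do not by themselves decide on chance.

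Immediate early genes, which respond within minutes to growth factors and handling, were lower in the replicate 1 samples of all 4 groups: all 15 tested were lower, with a median of -2.76, Fos at -3.99, Egr1 at -2.76 and Ier2 at -2.89. Skeletal muscle genes were higher there, with a median of 1.28 and 10 of 13 called, Myog at 4.46 and Myh3 at 6.29, and 8274 genes differed in all. Sex cannot separate these samples, since the number 1 samples expressed Xist in Atm-WT cells and Y-linked genes in Atm-KO cells. A term for it, which left the immediate early genes at -2.62 ± 0.0824, is therefore no test. Slide and array brightness partly separate them, but with each as a term the immediate early genes stood at -2.78 ± 0.145 and -2.48 ± 0.131, against -2.62 without. So neither slide nor brightness accounts for the difference. A shared harvest or handling of the number 1 samples may explain it, which was not tested here.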
